A study of Sus scrofa with 24 samples.

How the data were processed

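Porcine aortic and aortic valve endothelial cells were isolated with collagenase, grown in medium with 10% serum and used at passage 5, per the labels. They were kept static or under 20 dyn/cm2 of steady laminar shear for 48 h. RNA of 2 conditions was labelled directly with Cy3 and Cy5 and hybridised at 65 C to Agilent 2-colour arrays. Per the labels, the authors' Feature Extraction software rejected saturated spots and spots beyond 1.42 interquartile ranges, subtracted local background, and normalised for dye bias and drift. The labels also state that statistics used spots measurable on all 6 arrays of a comparison at p under 0.005.

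The deposited table holds 1 value per probe and array, and the deposited values were read as log10 ratios of the 2 channels. The labels do not print this unit; it is inferred from the software and from the values' limit of 2 in size, at which 26 stand exactly (6.64 in log2). Every fold change depends on it. Array medians lie between 0 and 0.00767. Exact zeros were 139 to 2231 per array (0.957% to 15.4%), although on average 8.46 other values per array lay within 0.0001 of 0, so exact zeros were taken as not measurable. After this 12288 to 14380 of 14674 probes per array had a value, and the standard deviation per array was 0.513 to 0.777 in log2. Values were changed to log2 with the sign turned, so that they read first-named over second-named sample.

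The first-named sample of every comparison carried Cy3 and the second Cy5, per the labels, with no exchange of dyes. The direction assumes red over green, the definition that the scanner software uses for its log ratio. The labels name the dyes and do not state the numerator, and the table has no header that does. The plan fixed before the data were examined had 24 known flow genes decide if no label settled the direction, with values left as deposited if the exact binomial test did not pass. Of 17 measured, 10 had the expected sign (exact binomial test, two-sided p = 0.629; valve cells alone 11 of 17, p = 0.332; aortic cells alone 10 of 17, p = 0.629). That test settles nothing in either direction, the dyes and the software's definition were used instead, and if they mislead then every "higher" becomes "lower".

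Of the probes, 10474 have 1 gene symbol, 343 several and 3857 none. Probes of the same single symbol were averaged per array, giving 7230 named genes, 2637 of them from over 1 probe, and probes with several symbols or none were kept alone and counted among the genes. A gene was tested where it had a value on all 6 arrays of a comparison, or on all 24 for the interaction, and a gene's mean took only the probes with such values, so it can rest on fewer probes in the interaction than in a single comparison.

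Each comparison was fitted on its own 6 arrays in R 4.3.3 with limma 3.58.1 (statmod 1.5.0), testing the mean log2 ratio against 0. The slide was a random block, with a correlation between arrays of a slide of 0.411 for valve shear, 0.389 for aortic shear, 0.557 for the static and 0.469 for the sheared cell type comparison. The interaction was fitted on all 24 arrays with 1 mean per comparison (slide correlation 0.537). Errors are standard errors of that fit. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Slides carry the numbers 1 to 3 in each comparison, and 18 pairs of equally numbered slides were checked for a shared residual (r from -0.385 to 0.251 across genes, 4 above 0.1). In the 12 pairs that hold the same condition, with r turned where it stands on opposite sides, r ran from -0.212 to 0.385, again with 4 above 0.1. Pairing was to be used only if every pair exceeded 0.1, and the labels do not state it, so slides were treated as unpaired.

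Gene groups came from 35 lists of human symbols fixed before the data were examined, covering flow and stress responses, growth, matrix, calcification, signalling, metabolism, basic cell machinery and markers of endothelial and other cell types. They were tested by limma's camera on the moderated statistic with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison with at least 5 measured members, and again with the correlation estimated per list. Genes were named by a rule set at the same time. It took the 8 most positive and 8 most negative called genes with the same sign on all 6 arrays, up to 4 members of each described list with the smallest adjusted p, and 13 vascular genes given throughout. For the interaction both estimates had to share their sign, which left 14 genes. The same rule was applied to the static cell type comparison without slide 1 after the data were seen, and genes outside the rule stand beside another comparison's value.

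Dye-free contrasts were added after the data were seen, on 22 arrays without slide 1 of the static cell type comparison. Each subtracts the ratio of valve over aortic cells under shear from a shear comparison, or the mean of both shear comparisons from a cell type comparison. They remove a gene's dye bias where it is the same in both array sets, and they mix shear with cell type. Their list tests used the preset correlation only. In the valve shear contrast the sheared valve sample cancels as well, which leaves sheared aortic over static valve cells, so it does not test the valve shear response. Alternatives fixed beforehand were centring and scaling of arrays, no slide block, slide means, looser and stricter filters, separate probes, 1 shared fit, slide number as a replicate block, other thresholds, array weights, no moderation, each estimate of the interaction alone, and leaving out each slide in turn. Those chosen after the data were seen were exact zeros kept as values, the dye-free contrasts, slide 1 of the static cell type comparison with its sign turned, and the fits and list tests without it.

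The steps were tested on simulated data with 200 changed genes per fit. At a log2 size of 1 they recovered 80.7% for valve shear (9401 genes), 81.4% for aortic shear (9006 genes), 77.9% for the static (9502 genes) and 79.4% for the sheared (9810 genes) cell type comparison, and 86.3% for the interaction (7958 genes). At a log2 size of 0.5 the shares were 42.9%, 30.6%, 23.5%, 43.1% and 41%, and at 2 they were 95.5%, 97.1%, 100%, 98.3% and 98.5%. False calls among unchanged genes were 12, 7, 8, 11 and 9 in that order. The simulated slide correlation was 0.4, below the 0.557 of the static comparison and the 0.537 of the interaction. Errors were normal and held no shared dye bias, so these shares hold only for such data. Raw scanner signals are not in the table, so signal over background could not be used, and no array was left out of the comparisons as planned.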

Results

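Endothelial cells of the porcine aorta and of the porcine aortic valve were compared after 48 h in static culture or under steady laminar shear of 20 dyn/cm2, the drag that flowing blood exerts on the vessel and valve lining. RNA from 2 of these 4 conditions was hybridised together on each 2-colour array. The 24 arrays gave shear over static in valve cells, shear over static in aortic cells, valve over aortic cells in static culture, and valve over aortic cells under shear. Each comparison had 6 arrays on 3 slides, and 12288 to 14380 of 14674 probes per array had a measured ratio. The labels do not say whether slides are separate cultures, so p-values measure only the spread between these arrays and slides, and the small number of arrays limits the precision.

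Ratios are given so that a positive log2 value means more RNA in the sheared or the valve sample. This direction is likely, not stated: it rests on the dyes in the labels and on the scanner software's usual ratio of red over green. A test of known flow genes did not settle it (10 of 17 had the sign known for laminar flow, exact binomial p = 0.629), and with the opposite direction every sign would turn. The first-named sample always carried the green dye: the sheared one in the shear comparisons and the valve one in the cell type comparisons. Any dye bias of a gene that the authors' normalisation left would thus remain in every ratio. Of 7958 genes measured on all 24 arrays, 4258 (53.5%) had the same sign in all 4 comparisons, against 16.7% if the 4 conditions were ordered at random. A shear effect alike in both cell types and a cell type difference alike in both conditions would also raise this share. The share therefore does not measure dye bias. A dye bias would cancel in the difference between comparisons if it is the same in both array sets, which differ in their blank probes. All aortic shear arrays are in set A and all arrays of valve over aortic cells under shear in set B. In the dye-free contrast of aortic shear, a difference between the sets therefore cannot be told apart. Results of such dye-free contrasts are given beside the genes and gene groups. They mix shear and cell type, so a cell type difference alone can make or end a pass. In the contrasts of the cell type comparisons a shear response alone can do so too. Fold changes assume that the deposited values are base-10 logarithms, which is inferred from their range and the software.

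The first comparison asked which transcripts of valve endothelial cells respond to laminar shear. CYP1A2 and CYP1A1, cytochrome P450 enzymes induced through the aryl hydrocarbon receptor, rose 9.47-fold and 8.3-fold (log2 3.24 ± 0.159 and 3.05 ± 0.107, SE, n = 6 arrays; adjusted p = 0.000328 and 8.73e-05). GCLC, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, rose 6.02-fold (log2 2.59 ± 0.187, adjusted p = 0.000783). PRDX1, a peroxidase that removes hydrogen peroxide, rose 4.21-fold (log2 2.07 ± 0.134, adjusted p = 0.000783), and SLC7A11, the cystine importer that feeds glutathione synthesis, rose 4.02-fold (log2 2.01 ± 0.252, adjusted p = 0.00287). PRSS12, a secreted serine protease, fell by 2.55 on the log2 scale (SE 0.582, adjusted p = 0.0231), and ETV1, an ETS-family transcription factor, fell by 1.60 (SE 0.122, adjusted p = 0.000845).

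Other large increases in valve cells were CES1, a carboxylesterase (log2 2.64 ± 0.213), TKT, the transketolase of the pentose phosphate pathway (2.10 ± 0.147), and AKR1C1, an aldo-keto reductase (2.02 ± 0.221). Among the largest decreases were SCG2, a secretory granule protein (-1.54 ± 0.205), ENC1, an actin-binding protein (-1.5 ± 0.166), and ZFP36L1, which promotes decay of AU-rich mRNAs (-1.48 ± 0.308). KLHL25 (-1.36 ± 0.134), the mitotic kinase CDK1 (-1.35 ± 0.0997) and IGFBP3, a carrier of insulin-like growth factors (-1.34 ± 0.351, adjusted p = 0.0374), completed the group. All 16 of these genes had the same sign on all 6 arrays. Taking valve over aortic cells under shear from the valve shear comparison removes a dye bias that both array sets share, and also the sheared valve sample. What remains is sheared aortic over static valve cells, which does not test the valve response and is given as its own contrast further on.

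Of 41 measured cell cycle genes, 21 fell and 1 rose with shear in valve cells (24 and 1 adjusted over the list alone), with a median log2 ratio of -0.50 and a list test adjusted p = 7.71e-11. Examples were DLGAP5 (-1.32), HMMR (-1.24) and CKS2 (-1.07), which act in spindle assembly and mitotic progression. Genes for antioxidant defence shifted upward, with 11 of 23 members up and 2 down (12 and 2 adjusted over the list alone; median 0.51; adjusted p = 0.00248). That call was lost with adjusted p = 0.28 with an estimated correlation. TXNRD1, the cytosolic thioredoxin reductase, reached 1.76 (adjusted p = 0.00153) and FTL, the ferritin light chain, 1.27. Flow-induced genes of other endothelial systems also shifted upward (10 of 23 up, 1 down; 10 and 2 adjusted over the list alone; median 0.21; adjusted p = 0.0077). In the list for endoplasmic reticulum stress and protein folding, 11 of 21 members rose and 1 fell (13 and 1 adjusted over the list alone; median 0.30; adjusted p = 6.75e-05). ATF3, a stress-induced transcription factor, rose by 0.88 and P4HB, a protein disulfide isomerase, by 1.06. P4HB had similar values in aortic shear (0.978) and in the static (1.13) and sheared (0.881) cell type comparisons, so a dye bias is possible for it.

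Cytosolic ribosomal protein genes moved the other way in valve cells. Of 40 members, 16 fell and 1 rose (20 and 3 adjusted over the list alone), with RPS15A at -0.93 and RPS29 at -0.76 (median -0.25; adjusted p = 8.83e-05). Cholesterol synthesis and uptake genes shifted upward, 6 of 16 rising and 0 falling (7 and 1 adjusted over the list alone), with HMGCS1 at 1.17 and FDPS at 1.00 (median 0.35; adjusted p = 0.0151; adjusted p = 0.311 with an estimated correlation). Of 15 heat shock proteins, 6 rose and 1 fell (7 and 2 adjusted over the list alone), led by the small heat shock protein HSPB8 at 1.64 and the inducible chaperone HSPA1A at 1.15. This list had an adjusted p = 0.043, and adjusted p = 0.289 with an estimated correlation. HSPA1A (1.23, 1.15 and 1.22) and RPS29 (-0.85, -0.73 and -0.67) had similar values in aortic shear and in the static and sheared cell type comparisons. A dye bias would look like this, and no dye-free contrast tests valve shear. HSPB8 (-0.38 in aortic shear) and RPS15A (from -1.02 to -0.505) varied more.

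Several classical flow genes moved little. In valve cells KLF4, a flow-responsive transcription factor, rose by 0.31 (adjusted p = 0.0252) and THBD, the anticoagulant thrombomodulin, fell by 0.79 (adjusted p = 0.0171). THBD had similar values in the other comparisons (-1.09 in aortic shear, -0.87 in the static and -0.92 in the sheared cell type comparison), so a dye bias is possible. PECAM1, a junctional adhesion molecule, rose by 0.39 (adjusted p = 0.0398), and ACTA2, smooth muscle alpha-actin, by 0.85 (adjusted p = 0.00704). Both were above 0 in the other comparisons too (PECAM1 from 0.253 to 0.509, ACTA2 from 0.669 to 1.41), so a dye bias is possible for them. KLF2 stood at 0.13, the endothelial nitric oxide synthase NOS3 at -0.14, endothelin EDN1 at 0.25 and the leukocyte adhesion molecule VCAM1 at -0.30, and none passed (adjusted p = 0.421, 0.39, 0.12 and 0.137). Neither did the monocyte chemokine CCL2 (-0.18), VWF (-0.32), CDH5 (0.15) or TAGLN (-0.08), and ICAM1 was not measured on all 6 arrays.

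By limma, 1022 genes rose and 718 fell with shear in valve cells, of 9401 tested. Leaving out slide 2 lowered the count from 1740 to 573 and ended the calls of IGFBP3, SCG2 and PRSS12, while leaving out slide 3 gave 944 and ended those of SCG2 and PRSS12. The heat shock list was lost without any single slide (adjusted p = 0.0644, 0.0556 and 0.0764 without slides 1, 2 and 3), and the flow-induced and cholesterol lists were lost without slide 1 (adjusted p = 0.0644 and 0.0708).

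The second comparison asked the same of aortic endothelial cells. CYP1A1 and CYP1A2 rose 8.97-fold and 8-fold (log2 3.17 ± 0.185 and 3.0 ± 0.217, SE, n = 6 arrays; adjusted p = 0.00123 and 0.0023). GJA5, the arterial gap junction protein connexin 40, rose 7.01-fold (log2 2.81 ± 0.383, adjusted p = 0.00527), and TRPA1, a cation channel opened by electrophiles, rose 5.99-fold (2.58 ± 0.203, adjusted p = 0.0023). MGP, an inhibitor of vascular calcification, fell by 2.47 (SE 0.23, adjusted p = 0.0023), the largest decrease among the named genes. NR4A2, an orphan nuclear receptor, fell by 1.86 (SE 0.198, adjusted p = 0.00268).

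GCLC (2.41 ± 0.251), TXNRD1 (2.05 ± 0.265) and PRDX1 (2.03 ± 0.217) rose in aortic cells, as did CHI3L1, a secreted chitinase-like glycoprotein (2.40 ± 0.444). ENPP2, the lysophosphatidic acid-producing enzyme autotaxin, fell by 1.82 (SE 0.342), SDC2, a heparan sulfate proteoglycan, by 1.81 (SE 0.172) and ENC1 by 1.77 (SE 0.197). FRZB, a secreted Wnt antagonist, fell by 1.69 (SE 0.268), the peptide hormone gene SST by 1.64 (SE 0.179) and SCG2 by 1.63 (SE 0.181). All 16 aortic genes had the same sign on all 6 arrays, and 12 passed in the same direction in the dye-free contrast. CHI3L1, ENPP2 and MGP did not pass there (adjusted p = 0.168, 0.143 and 0.144), and SST passed in the opposite direction (0.70, adjusted p = 0.0403).

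Flow-induced genes shifted upward in aortic cells, with 13 of 24 rising and 1 falling (13 and 2 adjusted over the list alone; median 0.51; adjusted p = 0.00151; dye-free adjusted p = 0.000886). They included PLPP3, a lipid phosphatase of the endothelial surface (1.34), and SLC7A11 (2.0). Cholesterol synthesis and uptake genes rose in 8 of 16 cases and fell in 0 (9 and 0 adjusted over the list alone), among them HMGCS1 (1.56), the fatty acid desaturase SCD (1.34) and EBP (1.05). Their median was 0.68 (adjusted p = 0.00151; adjusted p = 0.194 with an estimated correlation; dye-free adjusted p = 9.61e-05). Of 23 antioxidant defence genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone), with FTL at 1.19 and PRDX2 at 1.15 (median 0.27; adjusted p = 0.0196; adjusted p = 0.194 with an estimated correlation; dye-free adjusted p = 0.000403). Immediate early genes, which respond within minutes to stimulation, rose in 9 of 22 cases and fell in 2 (10 and 2 adjusted over the list alone; median 0.36; adjusted p = 0.0224), with IER3 at 1.48 and FOS at 1.27. That call did not hold with adjusted p = 0.303 with an estimated correlation or in the dye-free contrast (adjusted p = 0.623). Genes for endoplasmic reticulum stress and protein folding rose in 7 of 21 cases and fell in 1 (10 and 1 adjusted over the list alone; median 0.36; adjusted p = 0.0196; dye-free adjusted p = 0.309); ATF4, a stress-response transcription factor, reached 0.77, while ASNS, asparagine synthetase, fell by 1.12.

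Cell cycle genes fell in aortic cells too, 17 of 41 down and 0 up (21 and 0 adjusted over the list alone), including KIF23 (-1.32), PTTG1 (-1.30), CKS2 (-1.08) and the replication clamp PCNA (-0.82). Their median was -0.41 (adjusted p = 1.19e-06; adjusted p = 0.368 with an estimated correlation; dye-free adjusted p = 1.5e-11). Interferon response genes shifted downward, 7 of 24 falling and 1 rising (8 and 1 adjusted over the list alone), with IFI44 at -0.99, OAS2 at -0.78 and IFIT2 at -0.66 (median -0.47; adjusted p = 0.0103). That list had adjusted p = 0.572 with an estimated correlation and a dye-free adjusted p = 0.00026 in the same direction. Of 23 bone and calcification genes, 6 fell and 1 rose (8 and 2 adjusted over the list alone), with TNFRSF11B, the osteoclast inhibitor osteoprotegerin, at -0.99 and the osteogenic transcription factor MSX2 at 1.36. Their median was -0.21 (adjusted p = 0.0402; adjusted p = 0.054 with an estimated correlation; dye-free adjusted p = 0.436). Cytosolic ribosomal protein genes fell in 9 of 40 cases and rose in 2 (12 and 4 adjusted over the list alone; median -0.19; adjusted p = 0.00901; adjusted p = 0.368 with an estimated correlation; dye-free adjusted p = 6.86e-07).

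CCL2 rose 2.66-fold in aortic cells (log2 1.41 ± 0.108, adjusted p = 0.0023) and passed in the dye-free contrast (2.26, adjusted p = 2.97e-05). THBD fell by 1.09 (adjusted p = 0.00957; dye-free adjusted p = 0.728), and CDH5, the endothelial cadherin, rose by 0.35 (adjusted p = 0.0362; dye-free adjusted p = 0.000558). KLF2 (0.07), KLF4 (0.30), NOS3 (0.05), EDN1 (0.00), VCAM1 (-0.23) and ICAM1 (0.11) did not pass, nor did PECAM1 (0.25), VWF (-0.13), ACTA2 (0.67) and TAGLN (-0.52).

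In aortic cells limma called 1110 genes up and 752 down of 9006 tested, and 385 of the 1684 with a dye-free value passed both tests. The count of 1862 rested on slides 2 and 3: it was 3 without slide 2 (2136 at an unadjusted p under 0.05), 69 without slide 3 and 3875 without slide 1, with 2, 8 and 16 of the 16 named genes still passing. The antioxidant and bone lists were lost without slide 1 (adjusted p = 0.108 for each), and the interferon and ribosomal lists without slide 2 (adjusted p = 0.186 and 0.0627).

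**Figure D1:**
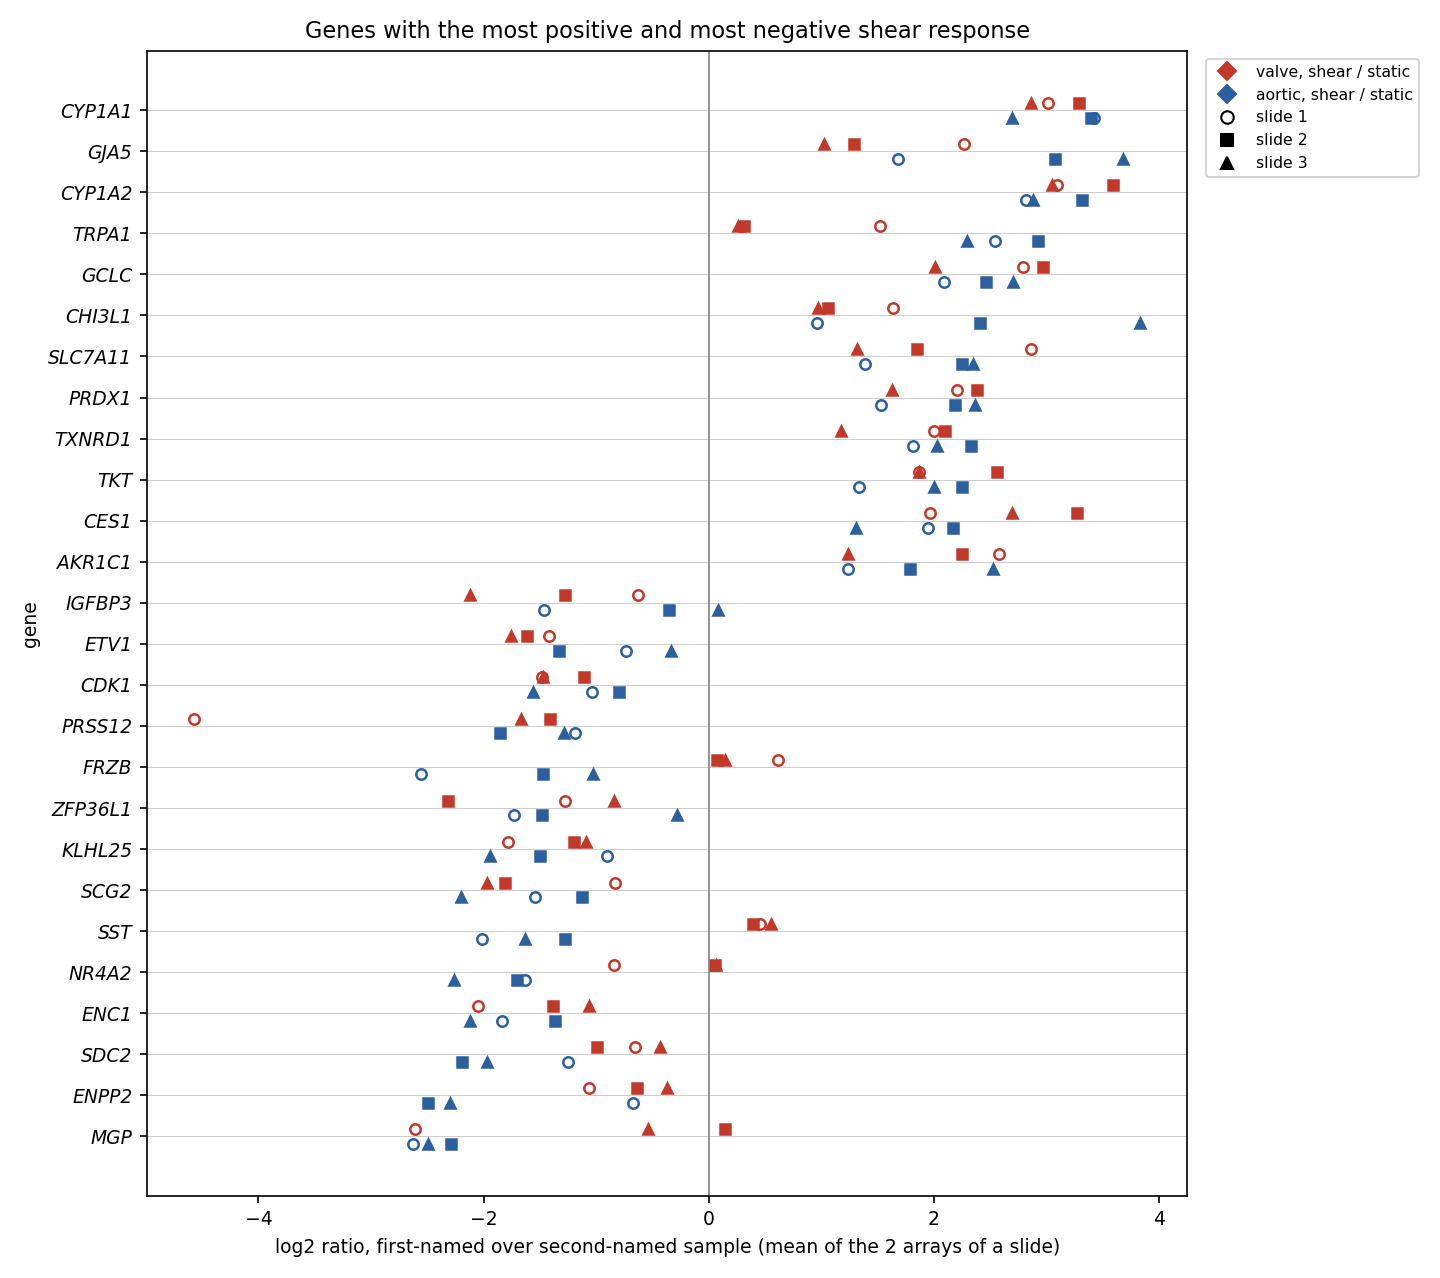
Log2 ratio of shear over static (x axis) for each gene (y axis) named for its size in valve cells (red) or aortic cells (blue); each point is the mean of the 2 arrays of a slide and the marker shape gives the slide. CYP1A1 averaged 3.05 in valve and 3.17 in aortic cells, while SST averaged 0.47 in valve and -1.64 in aortic cells.

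The shear responses of both cell types shared many genes. Among 8340 genes tested in both, 586 rose in both (126 expected from the counts alone), 349 fell in both (55.5 expected) and 3 moved in opposite directions (167 expected). The mean ratios correlated with r = 0.745 across genes, which are not independent replicates, and both sets of arrays carried the dyes the same way. CYP1A1, CYP1A2, GCLC, PRDX1, ENC1 and SCG2 were among the largest changes of both cell types. With slide 2 of both comparisons left out 2 genes were shared, and with slide 3 left out 25, against 935 with all slides.

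The third comparison asked how valve and aortic cells differ in static culture. Over all 6 arrays, CTSB, a lysosomal protease, was 3.28-fold higher in valve cells (log2 1.71 ± 0.18, SE, n = 6 arrays; adjusted p = 0.00765), and BGN, the small proteoglycan biglycan, 3.2-fold higher (1.68 ± 0.278, adjusted p = 0.0164). ACTA2 was 2.66-fold higher (1.41, adjusted p = 0.00715). It was also above 0 in valve shear (0.85) and aortic shear (0.669), so a dye bias may hold part of this value. RGS7, a regulator of G protein signalling, was 2.33-fold lower in valve cells (log2 -1.22 ± 0.163, adjusted p = 0.0101), and TXN, the redox protein thioredoxin, stood at -1.02 ± 0.17 (adjusted p = 0.0172).

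Among the other genes higher in valve cells were FKBP9 (1.77 ± 0.223), CSRP1 (1.72 ± 0.245), CHI3L1 (1.69 ± 0.381), the secreted growth factor GRN (1.69 ± 0.188), the glycolytic enzyme TPI1 (1.60 ± 0.168) and CRIP2 (1.58 ± 0.151). Lower in valve cells were PRUNE1 (-1.20), SYNGR3 (-1.19), TBC1D4 (-1.09), RPS15A (-1.02), RTN1 (-1.02) and CKS2 (-0.99). Of the genes named by size, those that passed in the same direction in the dye-free contrast were CTSB, BGN, RTN1, TXN and RGS7, and SYNGR3 and PRUNE1 had no dye-free value. FKBP9, CSRP1, CHI3L1, GRN, TPI1, CRIP2, TBC1D4, RPS15A and CKS2 are not among those that passed. Each had the same sign in valve and aortic shear (CRIP2 1.38 and 1.52), as did CTSB and BGN, so a dye bias may hold part of their values. THBD (-0.87, adjusted p = 0.011) and KLF4 (-0.69, adjusted p = 0.035) were lower in valve cells, and of these KLF4 passed in the dye-free contrast (-0.95, adjusted p = 0.0138). KLF2 (-0.08), NOS3 (0.09), EDN1 (0.26), VCAM1 (-0.33), ICAM1 (-0.25) and CCL2 (-0.64) did not pass, nor did PECAM1 (0.51), VWF (0.35), CDH5 (-0.15) and TAGLN (0.55).

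Integrin and junction genes were shifted toward valve cells, 8 of 30 higher and 0 lower (10 and 0 adjusted over the list alone), with the integrin subunit ITGAV at 1.56, the tetraspanin CD151 at 1.53 and GJA5 at 1.23 (median 0.28; adjusted p = 0.00618; dye-free adjusted p = 0.675). Oxidative phosphorylation genes were shifted toward aortic cells, 4 of 49 lower in valve cells and 1 higher (4 and 1 adjusted over the list alone), with the complex I subunit NDUFA1 at -0.72 and its partner NDUFV1 at 0.93. Their median was -0.18 (adjusted p = 0.0345; adjusted p = 0.405 with an estimated correlation; dye-free adjusted p = 0.00787).

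Slide 1 of this comparison ran against the other slides for the genes with the largest differences. LUM, a collagen-binding proteoglycan, measured 3.44 on slide 1 and -5.59 and -4.34 on slides 2 and 3, and CDH11, a mesenchymal cadherin, measured -3.63 against 4.14 and 4.22. The CDH11 values are means of 2 unlike probes, 1 of them at the limit of the deposited values on slides 2 and 3. Slides 2 and 3 correlated with r = 0.85 across genes, and slide 1 with them at 0.11 and -0.0451. Of 67 genes called on slides 2 and 3 with a log2 size of at least 2 and measured on all 24 arrays, 60 (89.6%) had the opposite sign on slide 1.

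Without slide 1, a choice made after the data were seen, the cell types differed far more. POSTN, the matricellular protein periostin, was at least 100-fold lower in valve cells, since all 4 remaining arrays stood at the largest ratio the deposited values can hold (log2 -6.64). LUM was 31.1-fold lower (log2 -4.96 ± 0.407, SE, n = 4 arrays; adjusted p = 0.00095), SLIT2, a guidance ligand, 20.8-fold lower (-4.38 ± 0.0865, adjusted p = 6.56e-06), and CXCL8, the neutrophil chemokine interleukin-8, 15.1-fold lower (-3.92 ± 0.214, adjusted p = 0.000342). CFI (-4.26), ALDH1A3, a retinoic acid-producing enzyme (-4.07), SST (-4.06) and the transcription cofactor DACH1 (-3.78) were also lower. CDH11 was higher (4.18 ± 0.121, adjusted p = 3.44e-05) as the mean of 2 unlike probes, at 1.71 and, on all 4 arrays, at the limit of 6.64. The transcription factor EBF1 was 9.59-fold higher (3.26 ± 0.178, adjusted p = 0.000342) and the cytoskeletal protein ADD3 8.8-fold (3.14 ± 0.0926, adjusted p = 3.44e-05). KRR1 (2.72), the Wnt inhibitor WIF1 (2.68), the gap junction protein GJA4 (2.48), CLDN11 (2.37) and CES1 (2.37) followed. CDH11, KRR1, DACH1 and CFI had no dye-free value, CES1 did not pass there (0.14, adjusted p = 0.826), and the other 11 passed in the same direction.

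Without slide 1, interferon response genes were lower in valve cells, 13 of 24 lower and 2 higher (15 and 3 adjusted over the list alone; median -0.69; adjusted p = 0.000276; adjusted p = 0.418 with an estimated correlation; dye-free adjusted p = 0.114). Oxidative phosphorylation genes were lower in 20 of 49 cases and higher in 6 (21 and 8 adjusted over the list alone; adjusted p = 0.0377; adjusted p = 0.121 with an estimated correlation; dye-free adjusted p = 0.00787). RNA splicing genes were higher in 14 of 31 cases and lower in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.0468; adjusted p = 0.255 with an estimated correlation; dye-free adjusted p = 5.96e-07), and the integrin and junction list did not pass (adjusted p = 0.0554).

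By limma, 566 genes were higher and 146 lower in valve cells in static culture over all 6 arrays, of 9502 tested, and 112 of the 683 with a dye-free value passed both tests. Without slide 1, 1806 were higher and 1183 lower of 9872 tested, with 767 of 2656 passing both tests, and with slide 1 turned 55 were higher and 106 lower. Without slide 2 or slide 3 limma called 0 genes (1259 and 1760 at an unadjusted p under 0.05), and the oxidative phosphorylation list was lost (adjusted p = 0.0866 and 0.134).

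The fourth comparison asked how the cell types differ under shear. POSTN was at least 80-fold lower in valve cells (log2 -6.32 ± 0.16, SE, n = 6 arrays, 3 at the largest ratio the values can hold; adjusted p = 9.02e-07). CXCL8 was 8.84-fold lower (-3.15 ± 0.326, adjusted p = 0.000647), TRPA1 7.88-fold lower (-2.98 ± 0.162, adjusted p = 3.19e-05) and COL3A1, a fibrillar collagen, 7.22-fold lower (-2.85 ± 0.135, adjusted p = 1.97e-05). CDH11 was higher (3.45 ± 0.143, adjusted p = 1.39e-05) as the mean of 2 unlike probes, which stood at 0.62 and 6.28, the latter at the limit on 3 arrays. CES1 was 10.9-fold higher (3.45 ± 0.123, adjusted p = 7.7e-06). MAF, a leucine zipper transcription factor, was 4.53-fold higher (2.18 ± 0.108, adjusted p = 2.09e-05).

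ADD3 (2.69 ± 0.238), CLDN11, a tight junction claudin (2.51 ± 0.265), HSPB8 (2.42 ± 0.18), the cytokine receptor IL17RB (2.40 ± 0.225) and EBF1 (2.37 ± 0.238) were higher in valve cells. DACH1 (-3.19 ± 0.254), ALDH1A3 (-3.12 ± 0.133), the imprinted retrotransposon-derived gene PEG10 (-3.06 ± 0.608) and SLIT2 (-2.86 ± 0.125) were lower. The 14 named genes with a dye-free value passed in the same direction there, and CDH11 and DACH1 had none. Of 31 RNA splicing genes, 13 were higher in valve cells and 2 lower (15 and 2 adjusted over the list alone), with the splicing factors SF3B2 at 0.97, U2AF1 at 0.91 and HNRNPH1 at 0.88 (median 0.34; adjusted p = 0.00688; dye-free adjusted p = 1.05e-08).

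THBD (-0.92, adjusted p = 0.00141), CCL2 (-0.85, adjusted p = 0.0283), ICAM1 (-0.53, adjusted p = 0.0387) and CDH5 (-0.38, adjusted p = 0.0352) were lower in valve cells under shear, and PECAM1 was higher (0.41, adjusted p = 0.0217). CCL2 (-1.47, adjusted p = 0.000611) and CDH5 (-0.63, adjusted p = 0.000456) also passed in the dye-free contrast, THBD and PECAM1 did not, and ICAM1 had no dye-free value. KLF2 (0.13), KLF4 (0.12), NOS3 (-0.18), EDN1 (-0.10), VCAM1 (-0.42), VWF (0.15), ACTA2 (0.90) and TAGLN (0.42) did not pass.

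Under shear limma called 1090 genes higher and 829 lower in valve cells of 9810 tested, and 489 of the 1701 with a dye-free value passed both tests, 210 higher and 279 lower. Leaving out slide 1 gave 849 and slide 3 gave 507 (237 higher and 270 lower), ending the call of PEG10 in each case and of EBF1 without slide 3, and the RNA splicing list was lost without slide 2 (adjusted p = 0.0947).

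**Figure D2:**
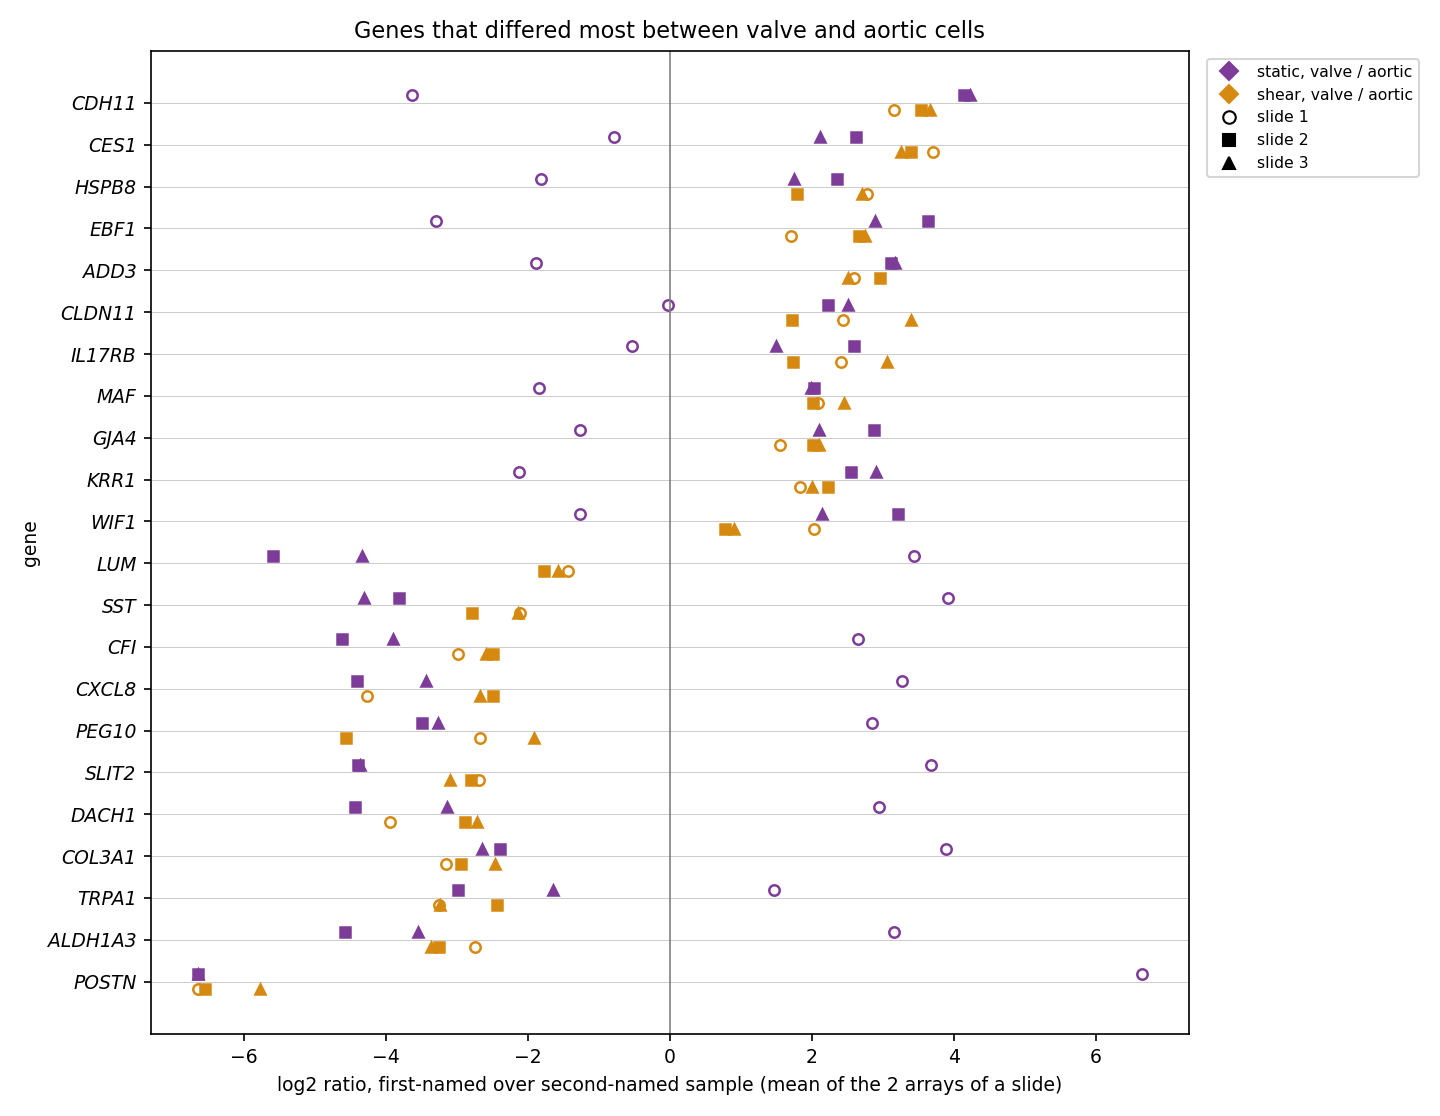
Log2 ratio of valve over aortic cells (x axis) for each gene (y axis) named for its size, in static culture (purple) and under shear (orange); each point is the mean of the 2 arrays of a slide and the marker shape gives the slide. LUM measured 3.44 on slide 1 of static culture and -5.59 and -4.34 on slides 2 and 3.

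Many genes that separated the cell types in static culture also did so under shear. Both sets of arrays carried the dyes the same way, so a remaining dye bias would add to this overlap and correlation. Of 9167 genes tested in both, 328 were higher in valve cells in both (63.6 expected), 94 were lower in both (12.2 expected) and 0 moved in opposite directions (63.7 expected), with r = 0.751 across genes. Without slide 1 of the static comparison, 833 were higher in both (202 expected), 592 lower in both (95.7 expected) and 4 opposite (279 expected), with r = 0.839. POSTN, SLIT2, ALDH1A3, CXCL8 and DACH1 were among the genes furthest below 0, and CDH11, EBF1, ADD3, CLDN11 and CES1 among those furthest above, in both. With slide 2 or slide 3 of both comparisons left out, 0 genes were shared in limma's calls (1259 and 1760 in static culture had an unadjusted p under 0.05), and with slide 1 of both left out 668 were.

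**Figure D3:**
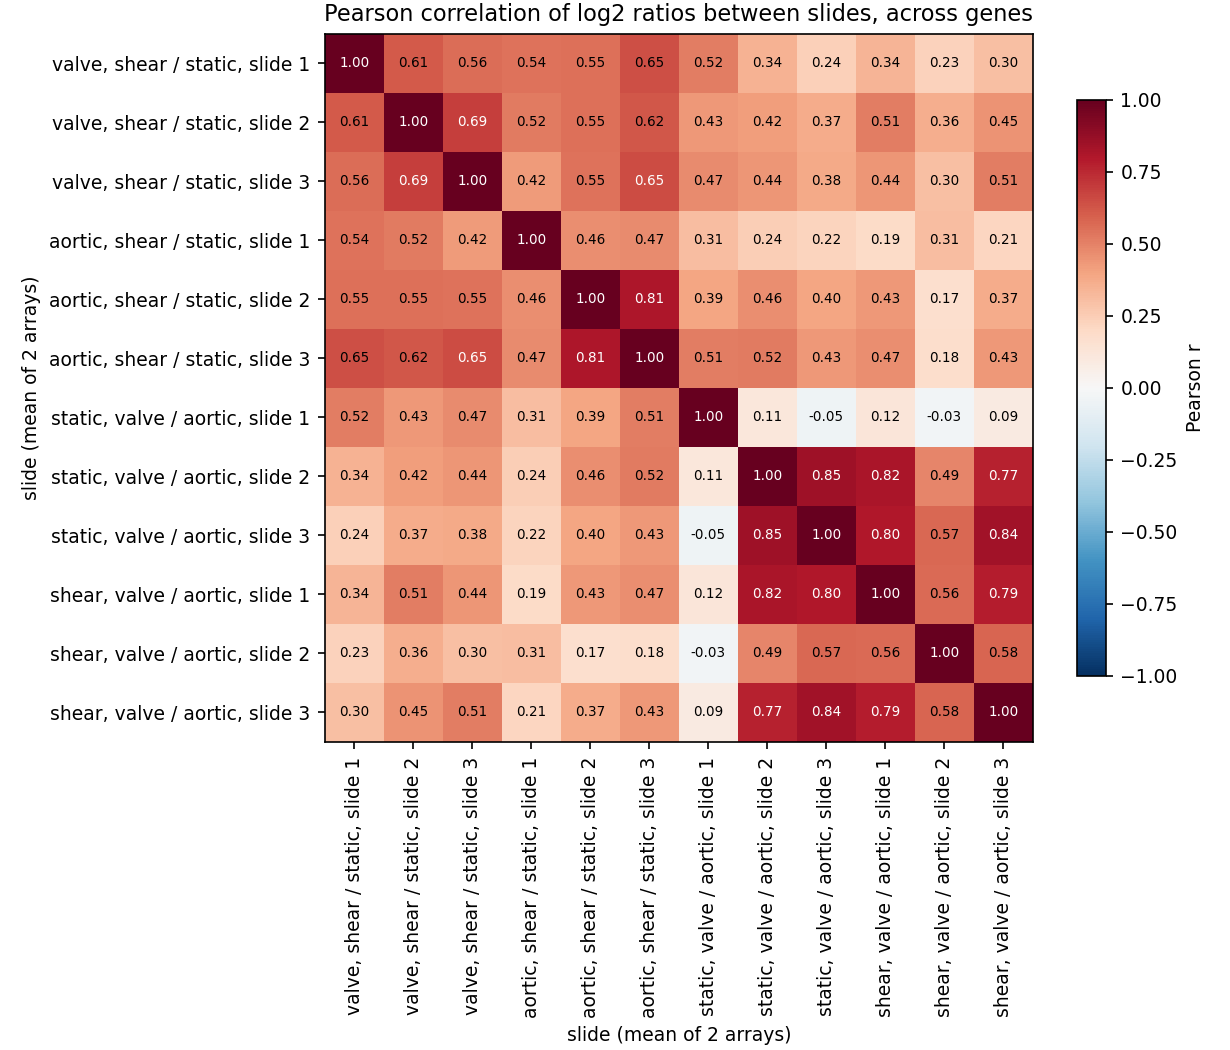
Pearson correlation across genes of the log2 ratios of each pair of the 12 slides (both axes list the slides; colour gives r). Slides 2 and 3 of valve over aortic cells in static culture correlated at 0.85, and slide 1 with them at 0.11 and -0.0451.

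The last comparison asked whether shear acted differently in valve and aortic cells. Its interaction value is the mean of 2 estimates, the difference in shear effect and the difference in cell type contrast. A dye bias cancels in each if it is the same in both array sets, which were unevenly spread over the comparisons. The interaction uses the probes measured on all 24 arrays, and the shear ratios given beside it come from the same fit. FST, which neutralises activins, had an interaction of 1.90 (log2, SE 0.363, n = 24 arrays; adjusted p = 0.0246): its shear ratio was 1.14 in valve cells and -0.78 in aortic cells. SLPI, a secreted protease inhibitor, stood at 1.33 (SE 0.221, adjusted p = 0.0117), with 1.76 in valve and -0.03 in aortic cells. CAV1, the coat protein of caveolae, stood at -1.11 (SE 0.23, adjusted p = 0.0312), with -1.29 in valve and 0.02 in aortic cells. PRDX6, a peroxiredoxin, stood at -1.01 (SE 0.173, adjusted p = 0.0117), with 0.13 in valve and 0.99 in aortic cells.

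FRZB (1.44, adjusted p = 0.0137) and TMSB15A (1.29, adjusted p = 0.0246) fell in aortic cells (-1.69 and -0.77), with 0.28 and 0.26 in valve cells. CYP1B1, a relative of CYP1A1, stood at -1.13 (adjusted p = 0.0147) with shear ratios of 1.06 in aortic and 0.06 in valve cells. MGST1, a microsomal glutathione transferase (0.85), and MAGED2 (0.78) rose in valve cells (0.78 and 0.99), with 0.27 and 0.17 in aortic cells. The caveolin CAV2 (-0.77) and FILIP1L (-0.78) fell in valve cells (-0.57 and -0.47), with 0.09 and -0.00195 in aortic cells. ACLY, which supplies acetyl-CoA for lipid synthesis, stood at -0.55 and fell in both cell types (-0.85 in valve, -0.42 in aortic). IFIT2, an interferon-induced gene, stood at 0.96 (adjusted p = 0.0261) and fell in aortic cells (-0.66; -0.11 in valve). PDE6D stood at 1.08 (adjusted p = 0.0423) on the 1 of its 2 probes measured on all 24 arrays, with -0.70 in valve and -1.64 in aortic cells. The aortic mean over both probes was -0.66, close to the valve value, so its difference in shear effect rested on 1 probe.

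Interferon response genes had a positive interaction as a group, with a median of 0.42 over 20 members and a list test adjusted p = 2.27e-06 (adjusted p = 0.291 with an estimated correlation). Of these, 1 passed upward and 0 downward (2 and 0 adjusted over the list alone), with IFIT3 at 1.19 (adjusted p = 0.2) and IFITM1 at 0.84. Cell cycle genes had a median of 0.14 (38 members, 0 passing; 1 and 0 adjusted over the list alone; adjusted p = 0.000428; adjusted p = 0.413 with an estimated correlation), KIF23 standing at 0.62. Glycolysis and hypoxia response genes had a median of -0.14 (20 members, 0 passing; 0 up and 1 down adjusted over the list alone; adjusted p = 0.00496; adjusted p = 0.156 with an estimated correlation), with lactate dehydrogenase LDHA at -0.86. Integrin and junction genes had a median of -0.14 (29 members, 0 passing; 0 up and 1 down adjusted over the list alone; adjusted p = 0.0485; adjusted p = 0.397 with an estimated correlation), with GJA5 at -1.28 (adjusted p = 0.0612). CCL2 (-0.90, adjusted p = 0.0822), KLF2 (0.14), KLF4 (0.41), NOS3 (-0.23), THBD (0.13), EDN1 (-0.05) and VCAM1 (-0.08) did not pass, nor did PECAM1 (0.02), VWF (-0.22), CDH5 (-0.21), ACTA2 (-0.17) and TAGLN (0.15).

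Of 7958 genes tested, limma called 26 with an interaction, 19 positive and 7 negative, and 617 had an unadjusted p under 0.05. From shear effects alone 24 were called, while cell type differences alone gave 0 (415 at an unadjusted p under 0.05) and slide means gave 0 (569 at an unadjusted p under 0.05). The count was 421, 0 (308 at an unadjusted p under 0.05) and 5 with slides 1, 2 and 3 of every comparison left out, and 96 without slide 1 of valve over aortic static alone, where the cell cycle (adjusted p = 0.0891), integrin (adjusted p = 0.224) and glycolysis (adjusted p = 0.0884) calls ended. Leaving out slide 2 of every comparison ended the interferon (adjusted p = 0.384), integrin (adjusted p = 0.745) and glycolysis (adjusted p = 0.0612) calls. Leaving out slide 1 of every comparison ended the glycolysis call (adjusted p = 0.288).

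**Figure D4:**
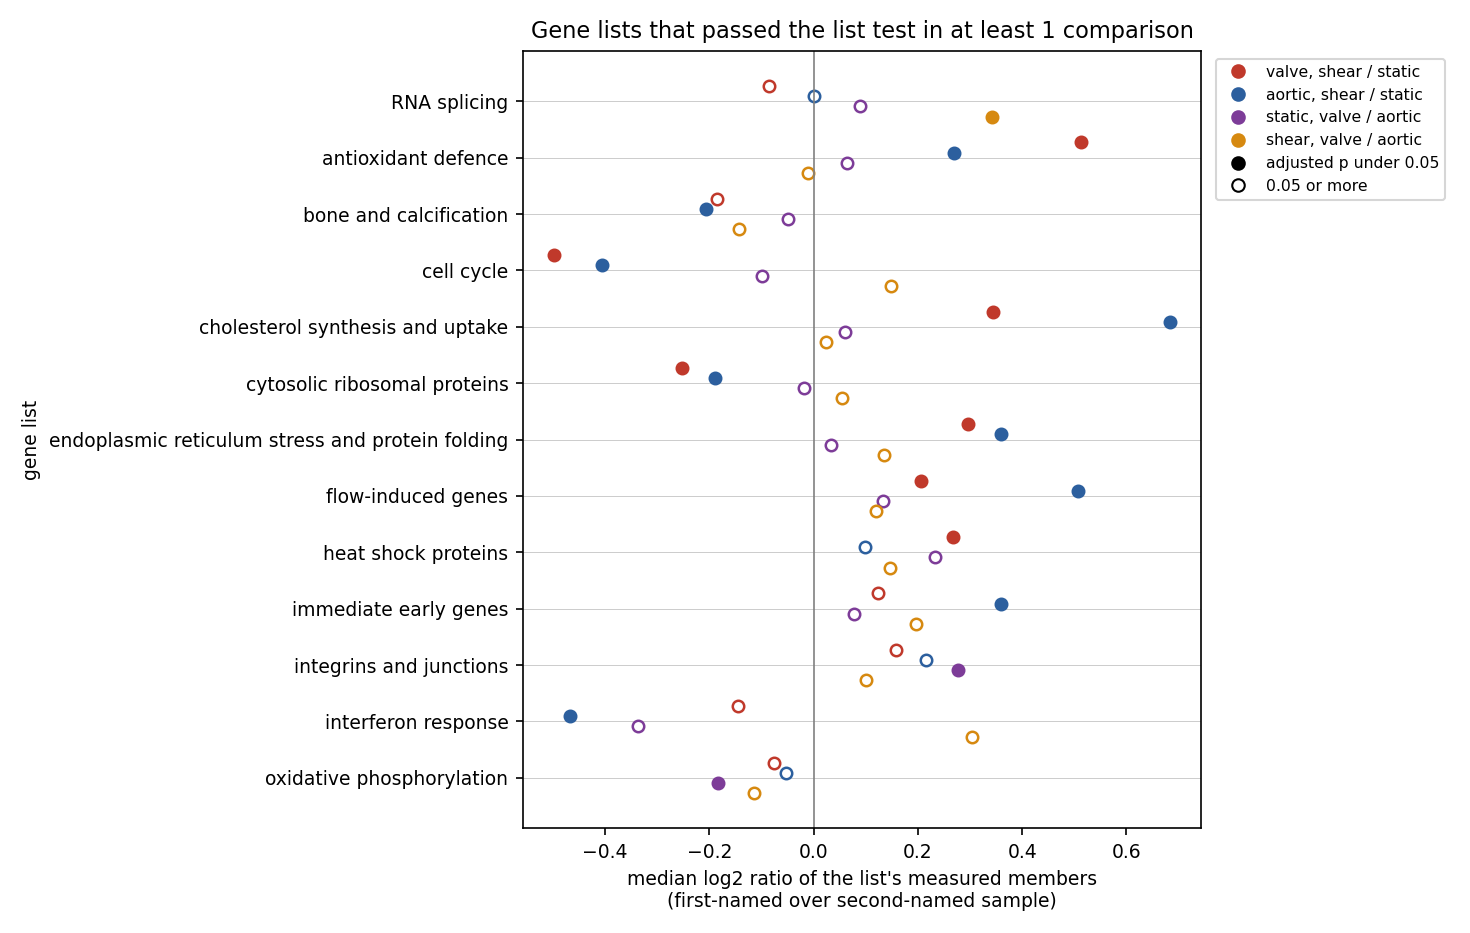
Median log2 ratio of the measured members (x axis) of each gene list (y axis) that passed the list test in at least 1 comparison; colours give the comparison and filled points an adjusted p under 0.05. Cell cycle genes had medians of -0.50 in sheared valve cells and -0.41 in sheared aortic cells.

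Sheared aortic cells were also set against static valve cells, a contrast that the arrays give by 2 routes. It is free of dye bias if that bias is the same in both array sets. The first route, valve shear over static minus valve over aortic under shear, gave 183 genes higher and 172 lower. The second, aortic shear over static minus valve over aortic in static culture, gave 115 higher and 75 lower, and 88 genes passed by both in the same direction (r = 0.572 across 7958 genes). These counts used all 24 arrays. On 22 arrays without slide 1 of the static comparison, a choice made after the data were seen, the routes gave 363 higher and 325 lower, and 462 higher and 455 lower. There 470 genes passed by both in the same direction (r = 0.746 across 8024 genes), and the values below are from that fit. CYP1A1 (1.54), CYP1A2 (1.97), GCLC (1.64), PRDX1 (1.45) and SLC7A11 (1.96) were higher and KLHL25 (-2.29), ENC1 (-2.90) and ETV1 (-2.60) lower by the first route. List tests here used the preset correlation only. Antioxidant defence genes were higher by each route (adjusted p = 4.2e-06 and 1.04e-06), while cell cycle (adjusted p = 1.01e-13 and 2.74e-05) and ribosomal protein genes (adjusted p = 4.99e-11 and 6.44e-06) were lower. RNA splicing genes were lower by each route (adjusted p = 4.59e-09 and 4.6e-06), and Notch signalling genes were higher (adjusted p = 0.0129 and 0.0417).

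The 4 comparisons close a loop, so that the valve over aortic ratio under shear should equal a sum of the other 3 with coefficients 1, -1 and 1. Across 7958 genes the fitted coefficients were 0.181 for valve shear, -0.224 for aortic shear and 0.82 for valve over aortic in static culture. Without slide 1 of the static comparison they were 0.321, -0.195 and 0.635, so the signs were as the loop requires and the sizes were smaller.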

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

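The tests of the interferon response below were chosen only after the result was seen; the interaction test and the exchange of slides were planned.

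The planned interaction test by limma called 26 genes for a shear effect that differed between valve and aortic cells. It called 0 with slide means (569 at an unadjusted p under 0.05) and 0 from cell type differences alone (415 at an unadjusted p under 0.05). Of 100 splits of the slides between the shear comparisons and between the cell type comparisons, 7 gave at least as many, the real one included, and the highest other count was 192. Chance is therefore not excluded for the number 26. A split with 192 genes, several times the real count, points to a structure of the slides; which structure was not tested.

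Among the 26 genes, FST (1.90), FRZB (1.44), SLPI (1.33), TMSB15A (1.29), PDE6D (1.08), IFIT2 (0.963), MGST1 (0.848) and MAGED2 (0.778) had a positive interaction in log2. A negative interaction was found for ACLY (-0.549), CAV2 (-0.768), FILIP1L (-0.779), PRDX6 (-1.01), CAV1 (-1.11) and CYP1B1 (-1.13). As groups, genes of the cell cycle (adjusted p = 0.000428), the interferon response (adjusted p = 2.27e-06), integrins and junctions (adjusted p = 0.0485) and glycolysis and hypoxia (adjusted p = 0.00496) also differed in their interaction from other genes with the preset correlation. None of the 4 passed with an estimated correlation (adjusted p = 0.413, 0.291, 0.397 and 0.156 in that order). Without slide 1 of valve over aortic static, the interferon list passed and the others did not (adjusted p = 0.0891, 0.224 and 0.0884).

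The interferon response genes had a median interaction of 0.42, the strongest of the 4 lists by its p. Slide 1 of valve over aortic cells in static culture is not the cause, since without it the list's adjusted p was 2.6e-10. An interferon response in single cultures or slides is a candidate explanation: leaving out slide 2 of every comparison gave an adjusted p of 0.384, against 1.49e-07 and 5.62e-07 for slides 1 and 3. The list's median was 0.864 on slide 2 of valve over aortic cells under shear and -0.104 and -0.228 on slides 1 and 3, and in aortic shear it was -1.1, -0.0504 and -0.482 on slides 2, 1 and 3. In valve over aortic cells in static culture it was -0.904, 0.385 and -0.677 on slides 2, 1 and 3, so that shift was not confined to slide 2. In valve shear it was -0.343, 0.117 and -0.305 in the same order. A true difference between the cell types in how shear affects interferon genes stays open and was not tested apart from it.

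Single arrays stood apart from the other 5 of their group by Dixon's test for 13 of 196 quantities tested, and chance gives such a result in about 1 in 20 groups, or 9.8 of 196. In valve shear over static, the IGFBP3 ratio was -2.91 on 1 array (next -1.34) and HYOU1 was 0.385 (next 0.631). In aortic shear over static, CYP1A2 was 3.89 (next 2.99), TXNRD1 1.06 (next 2.02), PRDX1 1.02 (next 2.05), ATF4 0.199 (next 0.777), FGF2 -0.195 (next -0.572) and VWF -1.19 (next -0.058). The spread of all log2 ratios in that comparison was 0.71 on 1 array. Valve over aortic cells in static culture held TBC1D4 at -0.485 (next -1.1) and CCL2 at -1.19 (next -0.638). Under shear PEG10 was -5.95 (next -3.17) and KLF2 -0.146 (next 0.13).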

How the results depend on the processing

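The settings chosen only after the data were seen were exact zeros kept as values, the dye-free contrasts, and slide 1 of valve over aortic static turned or left out alone, also in aortic shear over valve static. Centring, scaling, the looser and stricter filters, separate probes and the unadjusted threshold of 0.005 left every count of called genes within 1.5 times its main value, except that the last gave 130 interaction genes. The cause was not tested for the changes below, except that leaving out slides or averaging arrays leaves fewer values and the stricter rule is a subset by construction. Fewer values do not account for counts that rose. Without slide 1 the count rose from 1862 to 3875 for aortic shear, from 712 to 2989 for static and from 26 to 421 for the interaction. In the sheared cell type comparison it fell from 1919 to 849.

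Without the slide block limma called 2710 genes for valve shear, 3015 for aortic shear, 2158 for the static and 3205 for the sheared cell type comparison, and 137 for the interaction. With slide means the counts were 494, 282, 0 (2043 at an unadjusted p under 0.05), 1133 and 0 (569 at an unadjusted p under 0.05). A log2 size of at least 1 left 225, 291, 157, 300 and 9. Calls that also passed the dye-free contrast numbered 318 (142 higher, 176 lower), 385, 112 and 489 (210 higher, 279 lower), the first of them in a contrast without the sheared valve sample. In valve shear and the sheared cell type comparison the balance of higher and lower thus turned. Array weights gave 3379 for aortic shear, 2465 for static and 177 for the interaction, and no moderation gave 1675 for static and 117 for the interaction. Exact zeros kept gave 1237 for aortic shear, and 1 fit of all 24 arrays 2097 for static. The slide numbers did not meet the rule for pairing (18 pairs, r from -0.385 to 0.251, 4 above 0.1), and with slide number as a replicate block the counts were 1549, 1861, 2141 for static, 1700, and 31 for the interaction.

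Leaving out each slide in turn gave 573 to 1912 genes for valve shear, 3 to 3875 for aortic shear, 0 to 2989 for static, 507 to 2812 under shear and 0 to 421 for the interaction (beside the counts of 0, 1259 or more and 308 genes had an unadjusted p under 0.05). The shared shear genes ranged from 2 to 1304 and the shared cell type genes from 0 to 668. Loop coefficients ranged from 0.132 to 0.324 for valve shear and from -0.213 to -0.0232 for aortic shear. Lists passing ranged from 4 to 7 for valve shear, 1 to 3 for static and 0 to 5 under shear.

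Slide 1 of valve over aortic static turned gave 161 genes (55 higher, 106 lower, the reverse balance of all 6 arrays), 4 lists and 59 interaction genes. Left out alone, it gave 96 interaction genes, 1 interaction list, 1425 shared cell type genes and a loop coefficient of 0.321. The interaction was 0 genes from cell type differences alone (415 at an unadjusted p under 0.05). Aortic shear over valve static had 190 genes by the other route, against 355, and without slide 1 of static alone 688 by the first route and 917 by the other. With the inter-gene correlation estimated, 4, 2 and 1 lists passed for valve shear, aortic shear and static, and 0 for the interaction; zeros kept gave 14 for aortic shear and 1 for static.

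The genes that changed sign had not passed the threshold with all arrays, and of their turned values only TAGLN in valve shear without slide 1 passed (0.373, adjusted p = 0.0473). With array weights TAGLN was 0.027 in valve shear, KLF2 -0.0707 and VWF 0.0304 in aortic shear, KLF2 0.128 and NOS3 -0.0721 in static, KLF4 -0.0078 and EDN1 0.0457 under shear, and EDN1 0.036 and PECAM1 -0.0605 in the interaction. With slide 1 turned, KLF2 was 0.302, NOS3 -0.145, CDH5 0.0635 and TAGLN -0.0695 in static, and CKS2 -0.00817, KLF2 -0.0525, THBD -0.113, EDN1 0.0676 and ACTA2 0.348 in the interaction. Interaction values from shear effects alone were PFKL 0.0199, EDN1 0.252 and ACTA2 0.181, and from cell type differences alone THBD -0.0535, PECAM1 -0.104 and TAGLN -0.138. PECAM1 was -0.00963 with arrays centred and scaled and -0.0851 without slide 1 of static, and VWF was 0.164 in aortic shear with zeros kept.

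Sign changes with a slide left out gave these ranges. In valve shear CCL2 ran from -0.673 to 0.151 and TAGLN from -0.369 to 0.373. In aortic shear the ranges were KLF2 -0.172 to 0.227, EDN1 -0.172 to 0.172, ICAM1 -0.175 to 0.392, VWF -0.262 to 0.116 and TAGLN -0.922 to 0.164. In static KLF2 ran from -0.229 to 0.17 and NOS3 from -0.0437 to 0.225. Under shear KLF4 ran from -0.127 to 0.307, EDN1 from -0.287 to 0.196 and TAGLN from -0.124 to 0.998. In the interaction the ranges were EDN1 -0.161 to 0.128, VCAM1 -0.181 to 0.0145, PECAM1 -0.131 to 0.124, ACTA2 -0.523 to 0.24 and TAGLN -0.14 to 0.576.

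Of 2526 values of named genes under other settings, 2297 kept their direction and side of the threshold, 162 became weaker, 40 stronger and 27 changed sign. With a slide left out, 436 of 663 stayed, 193 became weaker, 17 stronger and 17 changed sign. Gene lists stayed in 53 of 75 and 52 of 69 cases and became weaker in 22 and 17. Signal over background is not in the deposited values, so its effect on weak genes could not be measured.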

Other observations

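The tests of slide 1 and of the component shared by the 4 comparisons were chosen only after the result was seen; the gene lists were planned.

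Endothelial identity genes did not shift as a group. With shear, 3 of 25 rose and 2 fell in valve cells (3 and 2 adjusted over the list alone; adjusted p = 0.696) and 6 of 24 rose and 3 fell in aortic cells (6 and 4 adjusted over the list alone; adjusted p = 0.747), and between cell types the adjusted p was 0.868 in static culture and 0.642 under shear. Markers of other cell types did not pass in these comparisons either. Of the fibroblast and valve interstitial markers, 0 of 17 rose and 2 fell in sheared valve cells (0 and 2 adjusted over the list alone; adjusted p = 0.0787), and 1 of 12 rose and 4 fell in aortic cells (1 and 5 adjusted over the list alone; adjusted p = 0.0694). In valve over aortic cells under shear 4 of 18 were higher and 4 lower (5 and 4 adjusted over the list alone; adjusted p = 0.398), although POSTN, which valve interstitial cells make, was among the furthest below 0 at -6.32. Smooth muscle and myofibroblast markers were higher in valve cells in 5 of 19 cases in static culture and lower in 0 (8 and 2 adjusted over the list alone; adjusted p = 0.246). Leukocyte markers had adjusted p = 0.379 and 0.139 in valve and aortic shear, epithelial and mesothelial markers 0.497 and 0.0748, and cardiomyocyte markers 0.212 and 0.552. Arterial and venous identity genes gave 0.225 and 0.492, and genes of endothelial-mesenchymal transition and valve development 0.416 and 0.962.

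Inflammatory and matrix genes were mixed. Flow-repressed genes, known from other endothelial systems, rose in 6 of 26 cases and fell in 4 in valve cells (8 and 5 adjusted over the list alone; median 0.22; adjusted p = 0.225), and rose in 7 of 25 and fell in 3 in aortic cells (7 and 3 adjusted over the list alone; median 0.19; adjusted p = 0.148). The list passed upward in sheared aortic over static valve cells (adjusted p = 0.0129) and in the dye-free contrast of aortic shear (adjusted p = 0.00483). CXCL8 belongs to this list and rose by 1.56 in valve and 1.90 in aortic cells, while ANGPT2, a regulator of vessel remodelling, fell by 0.96 and 1.14. Inflammation and leukocyte adhesion genes rose in 6 of 37 valve and 6 of 38 aortic cases and fell in 1 each (6 and 1 adjusted over the list alone in each; adjusted p = 0.39 and 0.209). Fibrillar collagens and matrix glycoproteins under shear were higher in valve cells in 5 of 34 cases and lower in 9 (5 and 9 adjusted over the list alone; adjusted p = 0.254), and Notch signalling genes were higher in 0 of 13 and lower in 4 (0 and 4 adjusted over the list alone; adjusted p = 0.0816). Each of these lists passed downward in the dye-free contrast by the list test (adjusted p = 0.0206 and 0.00477). That contrast subtracts the mean shear effect, so a rise with shear also lowers it and the pass does not show a shift toward aortic cells. In valve and aortic shear the adjusted p was 0.225 and 0.311 for oxidant production, 0.864 and 0.19 for growth arrest and p53 targets, 0.259 and 0.671 for basement membrane, and 0.637 and 0.091 for matrix proteases and inhibitors. It was 0.776 and 0.492 for cartilage, 0.379 and 0.747 for TGF-beta and BMP signalling, 0.282 and 0.747 for vasoactive and coagulation genes, 0.871 and 0.962 for the actin cytoskeleton, and 0.151 and 0.122 for the proteasome.

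Slide 1 of valve over aortic cells in static culture ran opposite to slides 2 and 3. An exchange of its 2 samples against the label may be the cause: of 36 genes with large cell type differences under shear, 97.2% had the opposite sign on that slide. The array set with its own blank probes did not shift these probes by itself. In valve shear, split over the same sets, their shift was 0.0156 of that seen here. Both samples there are valve cells, so a turn of channels in an array set would hardly move these genes. Across all genes, slide 1 of valve shear correlated at 0.61 and 0.557 with slides 2 and 3, which correlated at 0.688 with each other. That gives no sign of such a turn in valve shear. It cannot exclude one, since the component that all slides share also raises these correlations. An exchange of cells in every slide numbered 1 is excluded by another set, 67 genes with large differences on slides 2 and 3 in static culture. Of these, 0% were turned on slide 1 of valve over aortic cells under shear. A wrong label of another kind was not tested and stays open. With the slide turned 161 genes passed. That count cannot decide, since turning also reverses the component that the slide shares with the shear comparisons (r = 0.545 with the mean shear effect).

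The 4 comparisons shared a component, on which all 12 slides had the same sign and which held 51.3% of the sum of squares. Dye bias left in the values is a candidate explanation, since comparisons that hold a shared RNA on opposite sides would correlate below 0 through it. Aortic shear correlated at 0.419 across genes with valve over aortic cells under shear. Valve shear correlated at 0.444 with slides 2 and 3 of the static comparison, slide 1 left out. Another candidate is that genes raised by shear are also those higher in valve cells. Slide 1 of the static comparison, where cell type genes were turned, still correlated with the mean shear effect at 0.545. That argues against this candidate as the whole cause only if the samples of that slide were exchanged. A wrong label of another kind stays open for that slide, so its correlation cannot decide. A shear response common to both cell types stays open as a part of the correlation between valve and aortic shear (r = 0.762).

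Turning the sign of single slides gives 4 splits per comparison, which are too few for a share under 0.05. The real signs gave 1740 genes in valve shear (highest other 0), 1862 in aortic shear (highest other 0), 712 in static culture (highest other 161) and 1919 under shear (highest other 1). In each comparison 1 of the 4 splits, the real one, gave as many.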
